A study of Picea abies with 8 samples.

How the data were processed

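RNA of needles from 8 clones of Norway spruce (Picea abies), each 3 years old, was measured by RNA sequencing, with 1 library per clone. Sample titles begin with R for 4 clones and with S for the other 4. These letters were read as tolerant (resistant) and susceptible, because the series compares tolerant with susceptible clones, although no sample label spells the letters out. Clone numbers differ between the groups, so nothing pairs the samples. The replicate is the clone, and p-values set the difference between groups against the spread between clones of a group. With 1 library per clone, that spread also holds variation of the sampled plants and of library preparation. The labels name no harvest day, sequencing run or other batch, and no inoculation of the sampled plants.

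Needles were frozen in liquid nitrogen, RNA was extracted with CTAB and libraries followed standard Illumina procedures, per the labels' protocols. Reads were aligned with HISAT2, per the submitters' processing notes. The aligner's version, the counting program, its strand setting, the genome build and the annotation are not given in the sources used here. The authors deposited 1 table of raw counts per gene model, with whole numbers, no normalization and 1 column per clone. It holds 70736 gene models and 5 summary rows whose names are those that htseq-count writes. All columns matched a sample title, and 0 columns were left unused.

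The summary rows name no gene and stayed out of library sizes and tests. The no-feature row, for alignments assigned to no gene model, made up 60.3% to 61.0% of all counted rows per library. Alignments to several places made up 5.18% to 5.64%. Missing gene models would raise the no-feature share, as would a strand setting that mismatches the kit, whether or not the kit marks strand. The sources used here give neither, so the meaning of this share is open. The rows for ambiguous, unaligned and low-quality reads were 0 in every library. Counts in gene models were therefore 33.4% to 34.3% of each column. They summed to 21404783 for tolerant clone 1316 and to between 29212101 and 38583191 for the others. A count of 3, taken as the floor when a gene was at 0, corresponds to between 0.0781 and 0.144 CPM (counts scaled to a common library total, here the TMM-scaled total). Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Without a stated strand setting, reads of overlapping antisense models cannot be told apart, and reads of near-identical copies may be lost or split.

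The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts of all 8 libraries. Genes with few counts were removed with filterByExpr, libraries were scaled by TMM, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The filter left 36327 gene models, which held 99.8% of the counts in gene models. 20714 gene models had no count in any library. Fold changes are tolerant over susceptible, and their standard errors were computed from the fold change and the F statistic. CPM values used the TMM-scaled library totals. Distances between clones were Euclidean distances of log2 CPM with a prior count of 2 over the tested genes, compared by exact permutation of the group labels. A gene was called detected in one group only with at least 10 counts in every library of that group and 0 in every other library. It was called detected in one clone only with at least 20 counts there and 0 elsewhere. Pairs of clones differed in their counts by 44.9 to 103 times the sampling noise (chi-square per degree of freedom), so no library was a copy of another.

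The test was tried on simulated counts drawn from these libraries' means, totals and dispersions for 36327 genes. Of these, 200 were changed, all with a mean above 2 CPM, so recovery at lower levels was not tried. The test recovered 66% of the 4-fold and 4% of the 2-fold changes, each in the right direction. 6 of its 76 calls were unchanged genes. DESeq2 recovered 94% and 36%, and 83 of its 213 calls were unchanged genes. The shares recovered, and the shares of unchanged genes among the calls, depend on how many genes were changed.

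Groups, tests, alternatives and the rule for named genes were fixed before the data were examined. Where gene models have no names, the rule takes the 2 with the smallest p in each direction among genes past the threshold whose groups do not overlap. The deposited table pairs no gene model with a name, and no table of names was used here. The 24 gene lists planned on defence, cell walls, photosynthesis and other functions could therefore not be matched, and none was tested. Alternatives were other scalings, other count filters, DESeq2 1.42.0, limma-voom (limma 3.58.1) with and without sample weights, a robust prior, other distances and leaving out each clone in turn. An adjusted p threshold of 0.1, thinning of all libraries to 21404783 counts, and the library total as a covariate were added after the data were seen.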

Results

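Needle transcriptomes were compared between 4 Norway spruce clones classed as tolerant and 4 classed as susceptible to Heterobasidion parviporum, a fungus that causes root and stem rot in conifers. The tolerant clones were 291, 1316, 1528 and 3037, and the susceptible clones were 1611, 1623, 3012 and 3313. Each clone was represented by 1 library, with 21404783 to 38583191 counts in gene models. Total counts averaged 30884388 ± 6480800 (SD, n = 4) in tolerant and 32930404 ± 4153400 (SD, n = 4) in susceptible clones, and this difference was within the spread between clones (exact permutation test, two-sided, p = 0.657). Tolerant clones had counts for 43075 ± 303 gene models and susceptible clones for 43309 ± 328 (SD, n = 4 each; exact permutation test, two-sided, p = 0.286). Gene models at 1 CPM or more numbered 29665 ± 572 and 30037 ± 470 (SD, n = 4 each; exact p = 0.400). The 10 most abundant gene models took 8.86% ± 0.73 of the counts in tolerant and 9.42% ± 0.98 in susceptible clones (SD, n = 4 each; exact p = 0.371). After Benjamini-Hochberg adjustment over 6 such library measures, no exact permutation p was below 0.480.

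The first question was whether the 2 classes of clones differed across the needle transcriptome as a whole. Clones of different classes lay further apart than clones of the same class. The distance in log2 CPM over 36327 gene models was 205 ± 8.74 between classes, against 196 ± 3.54 among tolerant and 191 ± 5.73 among susceptible clones (SD over pairs of clones). The difference between the mean distances between and within classes was 11.2 (exact permutation test, one-sided, p = 0.0286, the smallest that 35 splits allow). The first principal component held 21.5% of the variance and separated the classes, with tolerant clones at 31.4 to 77.3 and susceptible clones at -100.3 to -13.0. The second component (15.0%) set tolerant clones 291 and 3037 apart from 1316 and 1528. The closest pair of all was susceptible 1611 and 1623, at a distance of 181, and the next was tolerant 3037 and susceptible 3012, at 189. Without susceptible clone 1611 the difference fell to 6.43 and no longer passed (exact p = 0.0571). Over the 1000 most variable genes the exact p was also 0.0571.

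**Figure D1:**
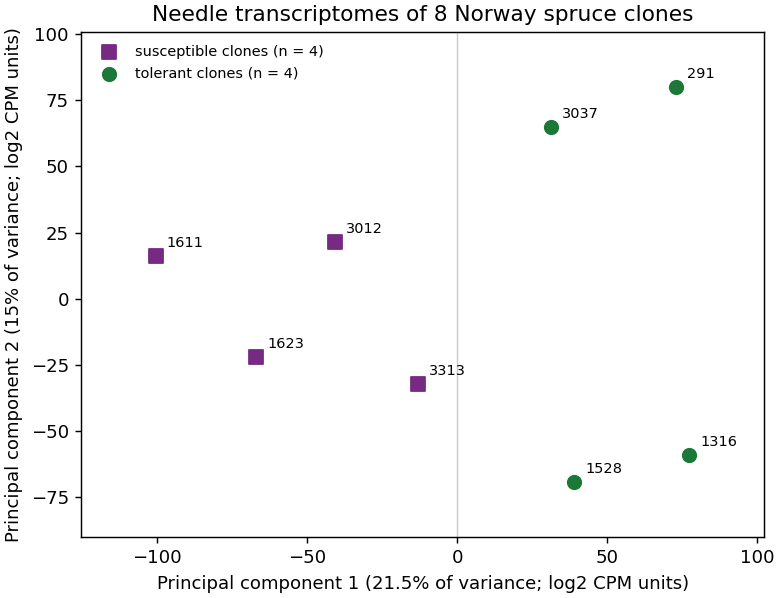
Principal components 1 (x axis, 21.5% of variance) and 2 (y axis, 15.0%) of log2 CPM for 4 tolerant clones (circles) and 4 susceptible clones (squares), each point 1 library labelled by its clone number. All tolerant clones lie above 0 on component 1 and all susceptible clones below 0.

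The spread among clones was not shown to differ between the classes. The mean distance among tolerant clones exceeded that among susceptible clones by 5.18, which was within what other assignments of the labels gave (exact permutation test over 70 assignments, two-sided, p = 0.343). The common biological coefficient of variation, the spread of a typical gene between clones of a class beyond counting noise, was 41.6%.

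The second question was which gene models differed between tolerant and susceptible needles. 11 of 36327 gene models passed the threshold in edgeR's quasi-likelihood test (adjusted p 0.0187 to 0.0441), 10 of them higher and 1 lower in tolerant clones. The 10 higher gene models exceeded their level in susceptible clones by 2.13-fold to 39.7-fold. 6 of them differed by over 4-fold and 4 by over 8-fold. Their mean levels in tolerant clones ran from 10.3 to 293 CPM, and in each of them every tolerant clone lay above every susceptible clone. All 11 also differed by over 2-fold.

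MA_467334g0010 had the smallest p-value. It stood at 25.3 ± 9.02 CPM in tolerant and 1.29 ± 0.35 CPM in susceptible clones (SD, n = 4 each), with 363 to 1204 counts per tolerant library and 25 to 63 per susceptible library. Its log2 fold change was 4.28 ± 0.33 (SE), or 19.5-fold higher in tolerant clones (edgeR, adjusted p = 0.0187). MA_101835g0010 was the next, at 10.3 ± 1.85 CPM in tolerant and 2.59 ± 0.18 CPM in susceptible clones (SD, n = 4 each). Its difference was 3.97-fold (log2 fold change 1.99 ± 0.17, SE; edgeR, adjusted p = 0.0275). MA_8519251g0010 was the single gene model that was lower in tolerant clones, at 2.39 ± 0.31 CPM against 6.85 ± 0.78 CPM (SD, n = 4 each). Its log2 fold change was -1.52 ± 0.17 (SE; edgeR, adjusted p = 0.0441). The names, functions and positions of these gene models are not given in the sources used here.

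**Figure D2:**
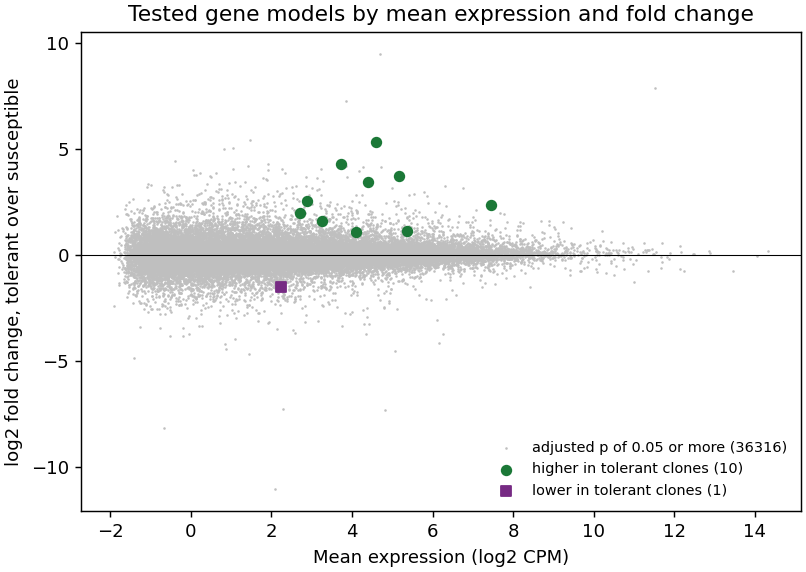
Mean expression (x axis, log2 CPM) and log2 fold change of tolerant over susceptible clones (y axis) for 36327 tested gene models, with n = 4 clones per class. Circles mark the 10 gene models past the adjusted threshold that were higher in tolerant clones, the square marks the 1 that was lower, and grey points did not pass.

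The differences extended to many gene models that did not pass singly. At an unadjusted p under 0.05, 4864 gene models (13.4% of those tested) differed, 2515 higher and 2349 lower in tolerant clones. In 3201 gene models (8.81%) the 4 tolerant clones lay all above or all below the 4 susceptible clones. Of these, 1624 were higher and 1577 lower in tolerant clones. A random split gives 2.86% on average. Gene models vary together, so a single split can lie far from that average, and this count was not made in other splits. At an adjusted p under 0.1, a threshold added after the data were seen, 171 gene models passed, 106 higher and 65 lower. The scaling centres the fold changes, so the balance of the 2 directions over all gene models was not itself tested.

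The count of 11 rested on the test and on the individual clones. DESeq2 called 1452 gene models, 831 higher and 621 lower in tolerant clones, including all 11. Leaving out 1 clone changed edgeR's count to 0 without 1611, to 1 without 291, 1316 or 3037, to 4 without 3313, to 5 without 3012, to 7 without 1528 and to 18 without 1623. Without 1611, where edgeR called 0, 3924 gene models had an unadjusted p under 0.05, 3261 of them among the 4864. With all libraries thinned to the smallest total, edgeR called 6, and with the library total as a covariate it called 1. The log2 fold changes of MA_467334g0010, MA_101835g0010 and MA_8519251g0010 were 4.28, 2.01 and -1.70 after thinning and 4.41, 1.99 and -1.55 with the covariate. MA_467334g0010 stayed past the threshold in 6 of the 8 fits without a clone, and not without 1611 (edgeR, adjusted p = 0.108) or 3037 (edgeR, adjusted p = 0.0648). Its log2 fold change was 4.13 without 1611 and 4.23 without 3037. MA_101835g0010 stayed past the threshold in 2 of 8 and MA_8519251g0010 in 0 of 8, with edgeR adjusted p-values up to 0.119 and 0.160. Their log2 fold changes in these fits were 1.89 to 2.08 and -1.59 to -1.44. The direction of all 11 gene models was the same under each of 19 alternatives. Since their classes did not overlap, leaving out a clone could hardly turn a direction, so this adds no support.

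**Figure D3:**
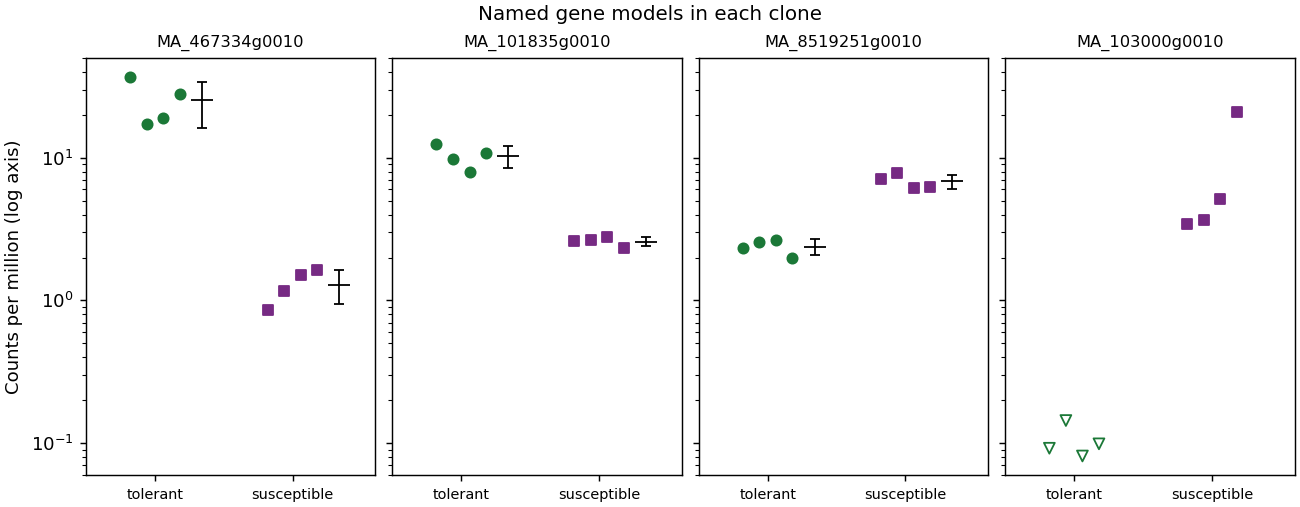
Level of 4 gene models (y axis, CPM on a log scale) in tolerant clones (circles) and susceptible clones (squares), each point 1 clone; bars give the mean ± SD (n = 4) and are left out for MA_103000g0010, whose susceptible SD exceeds the mean. Open triangles mark libraries with 0 counts, drawn at the level of 3 counts, and in each gene model the classes do not overlap.

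The third comparison asked which gene models had transcripts in one class and none in the other. 2 gene models had at least 10 counts in every susceptible library and 0 in every tolerant library, and 0 gene models showed the opposite. Both lie outside the rule for named genes and were chosen after their values were seen. MA_103000g0010 had 100 to 807 counts per susceptible library, or 8.31 ± 8.49 CPM (SD, n = 4). It was at least 80.0-fold lower in tolerant clones when these are set to the floor of 3 counts per library. Clone 3313, at 21.0 CPM, decided this mean: without it the level was 4.08 ± 0.93 CPM (SD, n = 3) and the bound 39.3-fold. MA_164038g0010 had 24 to 62 counts per susceptible library, or 1.11 ± 0.39 CPM (SD, n = 4), and was at least 10.7-fold lower in tolerant clones. Neither passed in edgeR (adjusted p = 0.0908 and 0.0686). Other splits of the 8 libraries gave as many such gene models often: 15 of 35 splits, the real one included, gave 2 or more. Leaving out clone 3012 turned the direction: 5 gene models were found in tolerant clones only and 2 in susceptible clones only. These numbers were 3 and 4 without clone 3037, and 1 and 3 without clone 1611.

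Transcripts seen in a single clone were found in every library. 69 gene models had at least 20 counts in 1 clone and 0 in the other 7. Their number was 7 in clone 291, 6 in 1316, 11 in 1528 and 12 in 3037 among tolerant clones. Among susceptible clones it was 3 in 1611, 10 in 1623, 7 in 3012 and 13 in 3313. The ranges of the classes overlapped, and no test was made of these counts.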

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

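None of the tests in this part was chosen before its result was seen. Of 24 sets of 4 clones examined for a value standing apart, 2 stood out, where chance gives about 1 in 20. MA_103000g0010 stood at 21.0 CPM in susceptible clone 3313, against 3.42 to 5.14 CPM in the other 3 susceptible clones. Tolerant clone 1316 had counts in 66 of the 143 gene models that were switched on or off between clones (described under other observations), against 84 to 87 in the other tolerant clones. With every library thinned to the total of clone 1316, the smallest, it had counts in 52 of 116 such gene models, against 65 or 66 in the other tolerant clones. Susceptible clone 3012 then had counts in 57, and the other susceptible clones in 67 to 70.

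Data outside the comparisons were also large in number. The alignments assigned to no gene model were the larger part of the counted rows of each library, with a median of 60.6% and a range of 60.3% to 61.0%. Alignments to several places had a median of 5.53% and a range of 5.18% to 5.64%. Neither share differed between the classes beyond the spread between clones (exact permutation test, two-sided, p = 0.143 and 0.229). What these reads are was not tested. Whether the kit marks strand, the strand setting of the counting and the completeness of the annotation are not known here. The share assigned to no gene model, like the gene counts, depends on them.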

How the results depend on the processing

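Of the alternatives below, the 0.1 threshold, thinning and the library total as a covariate were chosen after the data were seen. The 11 genes kept their direction under all 19 alternatives of the test, which was near certain beforehand because their classes did not overlap. The number of genes called was between 9 and 14 under the other scalings, count filters, limma-voom fits and the robust prior, and 8 to 11 of the 11 were among them. The number called moved to 1452 with DESeq2, 171 at an adjusted p under 0.1, 6 after thinning, 1 with the library total as a covariate, and to between 0 and 18 when each clone was left out. Without each clone, 0 to 4 of the 11 were still called: 4 among the 18 without 1623, and 0 with the single call without 3037. All 11 were among the DESeq2 calls, which leave out 2256 gene models with no adjusted p. Genes past 2-fold numbered 702 with DESeq2, 6 after thinning and between 0 and 18 without each clone. The separation of the classes passed in all settings but 2: it was 3.68 over the 1000 most variable genes, and between 6.43 (without 1611, the exception) and 13.8 (without 3037) when each clone was left out. Gene models detected in one class only numbered 5 with a minimum of 5 counts, and between 2 and 7 without each clone. Those in one clone only numbered 120 with a minimum of 10 counts and 23 with 50. The difference in total counts, which passed no test, ran from -3514200 to 1113900, turning positive without clone 1316. The differences in gene models above 0, gene models at 1 CPM and the share of the top 10, and the spread within classes, kept their direction and passed in 0 settings. MA_467334g0010 passed in 17 of 19 alternatives, MA_101835g0010 in 12 and MA_8519251g0010 in 7, while MA_103000g0010 passed in 1 (DESeq2). The cause of these changes was not tested, except that leaving out a clone leaves fewer samples. After thinning, 6 of the 11 kept their call. MA_8519251g0010 had a log2 fold change of -1.70 and an edgeR adjusted p of 0.0535, while the adjusted p of MA_467334g0010 was 0.0139 and that of MA_101835g0010 was 0.020. In counts simulated at the libraries' own totals, without thinning, edgeR recovered 66% of 4-fold and 4% of 2-fold changes. The gene list alternatives could not be run, since no gene model had a name.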

Other observations

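The counts of switched gene models, their tests, and the tests of co-variation were chosen after the data were seen, as was thinning to equal depth. Of the counts over other splits of the libraries, that of gene models detected in one class only was planned beforehand. The other counts over splits address patterns already seen. Some of the widest differences between clones lay in gene models that did not pass the test. MA_6521560g0010 had 176139 to 292835 counts in tolerant clones 291, 1316 and 1528, or 7036 to 8443 CPM. It had 369 counts (12.1 CPM) in tolerant clone 3037, and 107 to 2304 counts (3.66 to 64.0 CPM) in the susceptible clones. Its log2 fold change of 7.90 ± 1.86 (SE) had an adjusted p of 0.146 in edgeR. MA_69685g0010 and MA_69685g0030, whose identifiers share a stem, were both near 0 in tolerant clones, at 0 to 7 and 0 to 36 counts. In susceptible clones they had 112 to 596 and 195 to 3928 counts (edgeR, adjusted p = 0.0686 and 0.10). Their lowest level among susceptible clones was in clone 1611 for both. MA_125257g0010 had 63 to 1579 counts in tolerant and 1 to 12 in susceptible clones (log2 fold change 7.27 ± 1.25, SE; edgeR, adjusted p = 0.0876). MA_10216549g0010 had 3075 and 3401 counts in tolerant clones 291 and 3037, and 0 to 9 in the other clones (edgeR, adjusted p = 0.186). These gene models, and both gene models detected in susceptible clones only, lie outside the rule for named genes. They were the 7 with a log2 fold change beyond 6 in either direction.

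A further set of gene models was either silent or well expressed, depending on the library, with 1 library per clone. 143 gene models had 0 counts in at least 1 clone and at least 50 counts in each of the others. The number depends on that minimum: it was 337 with 20 counts and 69 with 100. Of the 143, 41 were silent in 1 clone alone and 23 were expressed in 1 clone alone. 16 were expressed in 4 clones, of which 1, MA_103000g0010, followed the classes, where chance gives 0.457. Clone 1316 alone was silent for 13 of them, and each other clone for 2 to 6. Unequal depth may add to this set but does not account for it, since 116 were found after thinning all libraries to the smallest total, 103 of them among the 143. The tolerant and susceptible classes did not order it: clones of different classes differed in 55.4 of the gene models and clones of one class in 55.1 (exact permutation test, one-sided, p = 0.514). Genes absent or silenced in a clone's genome, and alleles too diverged from the reference to align, stay open as explanations and were not tested. With 1 library per clone, a trait of the clone cannot be told from one of the sampled plant or its library.

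The broad difference between the classes was weighed against chance and depth. The real classes gave 4864 gene models at an unadjusted p under 0.05, and the highest of the other splits gave 3043, so 1 of 35 splits reached that number. The 11 calls of edgeR were likewise reached by 1 of 35 splits, with 6 as the highest other. The count past 2-fold equalled the count of calls in every split, so it is no further result. The real classes thus ranked first of 35 splits for the 4864 and for the 11, the best rank this test allows. That rank does not exclude chance, and both counts come from the same fit. For the 2 gene models detected in one class only, 15 of 35 splits reached the number, with 4 as the highest. Unequal depth would have had to remove most of the excess on thinning, and 4622 gene models were at an unadjusted p under 0.05 after it, 4201 of them among the 4864. Kinship within a class and shared growing or harvest conditions, which the labels do not give, stay open beside tolerance itself, so the difference may follow any of them.

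The gap between 11 calls in edgeR and 1452 in DESeq2 was weighed in the same way. DESeq2 called a median of 75 genes in the other 34 splits and 269 at most, so 1 of 35 splits reached 1452. A constant excess of calls whatever the split therefore does not account for the gap. The rank of the real split does not by itself exclude chance. In simulated counts, however, 39% of the DESeq2 calls were unchanged genes, or 83 of 213, against 7.89% for edgeR. Both shares depend on how many genes were changed, which was 200 of 36327 in the simulation. That number is unknown for the real classes, so the 39% cannot be carried over to the 1452. The simulated gap was far smaller than the real one, with 76 calls in edgeR against 213 in DESeq2. Recovery by edgeR (4% of 2-fold and 66% of 4-fold changes in the simulated counts) also depends on how many genes were changed. The real gap may hold both smaller changes that edgeR misses and false calls of DESeq2. The simulation does not account for its size, and the share of false calls among the 1452 stays unknown.

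One hypothesis concerned the 10 gene models higher in tolerant clones: that they may share variation between clones of the same class. Over the 45 pairs, the median correlation of deviations from the class means was 0.276. Counting noise lowers such correlations, as in MA_101835g0010 with 76 to 100 counts per susceptible library. This median alone therefore cannot decide whether the 10 are pieces of a single transcript. Pieces of a single transcript would differ by similar folds between the classes. The folds of the 10 ran from 2.13 to 39.7, which argues against a single transcript for the 10 together. Single pairs may still be such pieces. The pairs ran from -0.861 to 0.904, with a lower quartile of -0.185, so some varied in opposite directions. The median absolute correlation was 0.454, at percentile 99.1 of 10000 random lists matched on mean expression, whose median was 0.309. Genes are not independent replicates, and these 10 were chosen on the same libraries, so the excess is only a hint of shared variation.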
